A study of Mus musculus with 15 samples.

How the data were processed

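Total RNA of mouse bone macrophages, cultured for 14 days with 20 ng/ml M-CSF, was sequenced as paired-end reads on a BGISEQ-500 instrument after a SMARTER mRNA-Seq library preparation, per the labels. The 15 libraries comprised 5 of wild type (WT), 5 of a ROBO4 knockout (ROBO4_KO) and 5 of a VLDLR knockout (VLDLR_KO), and the labels gave the strain of all of them as C57BL6J. The submitters' processing notes listed HISAT and Bowtie2, without versions, and the genome build GRCm38.p6. The quantifier and the annotation release were not given in the sources used here.

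Per the file headers, the deposited gene and transcript tables held read counts for each library. The authors aligned the reads and quantified them per gene and per transcript without normalization, and the values are estimated counts (expected counts), since 92.6% of the gene counts, and not all of them, were whole numbers. A further set of columns held FPKM made by the authors. Their headers gave no unit, and FPKM was inferred because the ratio of count to value within a gene followed the library totals to within 1.0%. The same deposited table held averages of the counts over 6 sets of libraries, another kind of value, and these equalled the means of the libraries of 1 genotype and 1 form of sample code to within 0.01 for all 16886 genes. The authors' log2 fold changes between these sets, and their DESeq2 q-values (adjusted p-values), were read as given in the deposited table and were set beside the results computed here without entering them. A further gene table with the same counts, in which some symbols had been turned into dates, was not used here.

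The sample codes came in 2 forms, with the digit before the letter B (7 libraries) or after it (8 libraries). The labels do not say what the form means. WT replicates 3 to 5, ROBO4_KO replicates 1 and 2 and VLDLR_KO replicates 1 and 2 had the first form, and the other libraries had the second. Each form held libraries of all 3 genotypes, so every comparison was also made within each form and with the form as a covariate.

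Totals per library ranged from 18132866 to 19005966 estimated counts. There were 16886 genes and 54327 transcripts, of which 21660 had curated coding, 29067 predicted coding and 3600 predicted noncoding identifiers. Between replicates of the same group the chi-square per degree of freedom was 6.13 to 270, so the spread between libraries exceeded counting error. Intervals and floors given for counts cover counting error only, since the reads carried no molecular identifiers.

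Counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, which left 11668 genes, and libraries were scaled by TMM. A quasi-likelihood model with 1 coefficient per genotype was fitted to all 15 libraries, and the 3 pairs of genotypes were compared with two-sided quasi-likelihood F tests. Benjamini-Hochberg adjusted p-values under 0.05 over the tested genes are referred to as calls. Levels are CPM with library totals scaled by TMM, given as mean ± SD over the libraries of a group, and the standard error (SE) of a log2 fold change is its size divided by the square root of F. Transcripts were tested in the same way (30096 passed the filter), with a second adjustment over the transcripts of Slc17a5, Qk, Vldlr and Robo4. For genes with all libraries of a group at 0, the fold is a lower bound against a floor of 3 counts per library. With 1 to 3 counts in a group, the ratio is given with its exact counting interval at the 95% level.

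Before the data were examined, 30 gene lists were fixed. They covered macrophage identity, inflammatory cytokines, alternative activation, the interferon response, angiogenic and antiangiogenic factors, lipoprotein receptors and efflux, cholesterol synthesis, Wnt signalling, Slit and Robo signalling, RNA-binding proteins of circular RNA formation and the lysosome. They also covered the osteoclast, the cell cycle, MHC class II, hypoxia and glycolysis, complement, endoplasmic reticulum and oxidative stress, immediate-early genes, extracellular matrix and fibroblasts, osteoblasts and stroma, endothelium, neutrophils, dendritic cells, B cells, T and NK cells, erythroid cells and megakaryocytes, mast cells and basophils, adipocytes and sex-linked genes. The 24 lists with at least 5 tested members were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01. Estimated correlations and fry were run beside it, and members were also adjusted over the list alone. Annotation terms carried by the deposited gene table and held by 10 to 500 genes each were tested with one-sided Fisher's exact tests where at least 20 genes were called in a direction. Calls near a targeted gene were counted within 10 Mb and compared with two-sided Fisher's exact tests. Gene positions were taken from the deposited table (GRCm38). Of the genes, 16706 were placed both there and in the reference annotation, and 12272 started within 100 bp of the same position.

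The genes named were chosen by a rule also written before the data were examined. It always names Vldlr, Robo4, Slc17a5 and Qk. For each comparison it adds the 10 largest positive and 10 largest negative log2 fold changes among called genes with a mean of at least 1 CPM over all libraries and at least 5 CPM in the higher group, leaving out predicted or unnamed symbols and ribosomal pseudogenes. It then adds up to 4 called members per list with the smallest p, up to 2 members of the 3 lists with the smallest camera p even where not called, and the 5 transcripts with the smallest p per direction. A few genes that the rule names are not reported here. Genes named outside this rule are described as chosen after their values were seen.

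Alternatives covered upper-quartile and RLE scaling, DESeq2 1.42.0, limma-voom with and without sample quality weights, limma-trend on log2 FPKM with a pseudocount of 1, and no filter or a stricter one of at least 1 CPM in 5 libraries and a mean of 10 counts. Further alternatives fitted only the pair of groups compared, entered the code form or the share of Y-linked counts as covariates, used the codes as blocks, tightened the thresholds, and left out each library in turn. Alternatives added after the data had been seen left out WT replicates 1 and 2, VLDLR_KO replicates 1 and 2, WT replicate 3 with ROBO4_KO replicate 2, or the 3 libraries that lacked Y-linked counts, or entered both covariates together. For each comparison 100 splits of the libraries into groups of the same size were fitted again. For VLDLR_KO against ROBO4_KO, the 47 of them with as many libraries of each code form on both sides were also fitted with the form as a covariate.

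The procedure was tested on simulated data built from the deposited counts with 200 changed genes per comparison. At fold changes of 1.5, 2 and 4, edgeR recovered 17.9%, 47.8% and 87.9% of them in the design of VLDLR_KO against WT, 26.9%, 67.2% and 93.9% for ROBO4_KO against WT, and 20.9%, 71.6% and 80.3% for VLDLR_KO against ROBO4_KO. False calls numbered 6, 2 and 10 in these designs, against 29, 33 and 37 with DESeq2. For transcripts, 47% of the changes of 4-fold were recovered with 0 false calls. The test of effects that differ between the code forms (an interaction term) recovered 0%, 4.5% and 40.9% at fold changes of 1.5, 2 and 4. Its simulated spread included the difference between forms, so these shares do not describe the test on the real counts. In the test of annotation terms 1 term was planted, and 2 were called, 1 of them falsely. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and data.table (1.17.8), and plots with matplotlib 3.10.9. Circular RNAs were not analysed here, since the tables used here held linear genes and transcripts, and a count for the host gene does not measure a circular transcript. Xist and the raw reads were not used here.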

Results

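Bone macrophages of wild-type (WT) mice and of mice lacking the lipoprotein receptor VLDLR (VLDLR_KO) or the guidance receptor ROBO4 (ROBO4_KO) were compared by RNA sequencing after 14 days of culture with 20 ng/ml M-CSF, the growth factor that drives macrophages to survive and mature. Each genotype had 5 libraries, with 18132866 to 19005966 estimated counts per library, and 11668 genes were tested. The comparisons asked which genes change in macrophages without VLDLR, which change without ROBO4, and which differ between the knockouts. The series title also names QKI, the RNA-binding protein encoded by Qk, and a circular RNA of Slc17a5, so both genes were examined in every comparison. Unless another test is named, adjusted p values are from edgeR over the tested genes, log2 fold changes have standard errors (SE), and levels are CPM, mean ± SD over 5 libraries. The labels do not say that replicates are separate animals or cultures, so the p values measure only the spread between these samples.

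Vldlr, the targeted receptor gene (Entrez 22359, chromosome 19, 27201320 to 27254231, GRCm38), had few counts in every library. WT replicates 1 to 5 had 5, 9, 36, 10 and 14 counts, ROBO4_KO replicates 10, 38, 11, 2 and 6, and VLDLR_KO replicates 2, 5, 1, 9 and 9. Its log2 fold change was -1.44 in VLDLR_KO against WT (adjusted p = 0.255) and -1.28 against ROBO4_KO (adjusted p = 0.328), so no change was detectable at this depth. The sample codes had a digit before or after the letter B, and with the digit before B Vldlr had 1.05 ± 0.722 CPM in WT (n = 3), 1.25 ± 1.01 CPM in ROBO4_KO (n = 2) and 0.203 ± 0.133 CPM in VLDLR_KO (n = 2; -2.34 against WT, adjusted p = 0.109, and -2.60 against ROBO4_KO, adjusted p = 0.105). With the digit after B it had 0.397 ± 0.166 (n = 2), 0.341 ± 0.255 (n = 3) and 0.344 ± 0.252 CPM (n = 3), too few counts to be tested there, so the lower pooled level came from the first form. In that form single libraries were high, namely WT replicate 3 (1.87 CPM, the others 0.529 and 0.746) and ROBO4_KO replicate 2 (1.97 CPM, the other 0.533). Robo4, the other targeted gene (Entrez 74144, chromosome 9, 37401897 to 37414023), had 2 and 4 counts in WT replicates 1 and 2, 1 count in VLDLR_KO replicate 4 and 0 in the other 12 libraries, and was not tested. The counts of both targeted genes therefore check the genotype labels only weakly.

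Sample codes in 2 forms, with a digit before or after the letter B, split every genotype, and the labels do not explain them. The code form followed the first principal component of log2 CPM (34.3% of the variance), and VLDLR_KO libraries stood apart on the second (29.6%), at 24.74 to 74.14 against -15.61 to -32.39 for all others. Correlations within a genotype were 0.969 to 0.992 between libraries of the same form and 0.901 to 0.959 between forms. Values within each form are therefore given beside the pooled ones for Vldlr, Qk, Slc17a5 and some others. For some lists the mean log2 level per library is given, relative to the mean of all 15 libraries. Between forms, 4441 genes differed with genotype in the model.

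**Figure D1:**
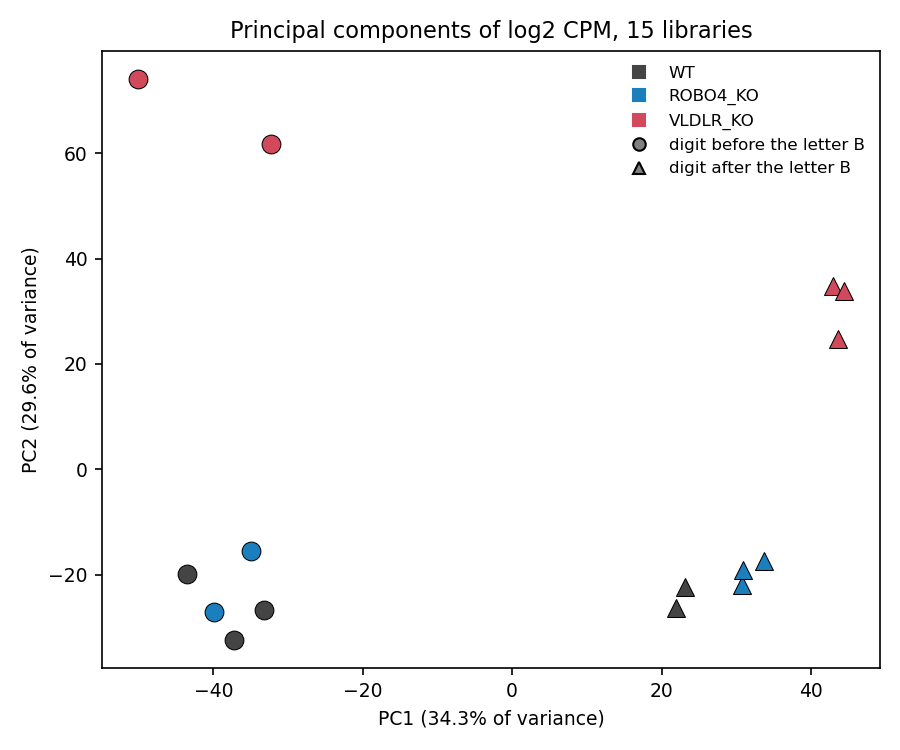
Position of the 15 libraries on the first and second principal components of log2 CPM of the tested genes, with groups in colours and the 2 code forms as circles (digit before B) and triangles (digit after B). The 5 VLDLR_KO libraries lie at 24.74 or more on the second component, and the 10 others lie at -15.61 or less.

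Macrophages lacking VLDLR had less Qk mRNA, which encodes the RNA-binding protein QKI, a splicing regulator (Entrez 19317, chromosome 17, 10187543 to 10319361, minus strand). Qk fell from 264 ± 28.9 CPM in WT to 187 ± 39.5 CPM in VLDLR_KO (n = 5 each; log2 fold change -0.50, SE 0.13, adjusted p = 0.0301), and ROBO4_KO had 277 ± 13.3 CPM. The difference between VLDLR_KO and ROBO4_KO was -0.57 (SE 0.13, adjusted p = 0.0169), while ROBO4_KO differed from WT by 0.07 (adjusted p = 1). Within the code forms Qk differed between VLDLR_KO and WT by -0.65 (adjusted p = 0.0501; digit before B) and -0.49 (adjusted p = 0.00765; digit after B), and between VLDLR_KO and ROBO4_KO by -0.79 (adjusted p = 0.0467) and -0.44 (adjusted p = 0.00769). The call against WT was lost without WT replicate 1 (adjusted p = 0.064), WT replicate 2 (0.0756), WT replicate 4 (0.0619) or VLDLR_KO replicate 5 (0.0632), and over all alternatives the adjusted p ranged from 0.00112 to 0.147. In the authors' deposited table, which compared genotypes within a code form by DESeq2, Qk had q = 0.0317 and q = 0.000644 for VLDLR_KO against WT.

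Transcripts of Qk were tested one by one. Whether they moved by different amounts was not tested. NM_021881.2 fell from 20.5 ± 2.28 to 8.88 ± 3.47 CPM in VLDLR_KO (log2 fold change -1.22, SE 0.27, edgeR adjusted p = 0.00201 over the transcripts of the key genes, 0.025 over all). NM_001159516.1 fell from 149 ± 10.6 to 96.5 ± 16.7 CPM (-0.64, SE 0.11, adjusted p = 0.00035 over the transcripts of the key genes, 0.00427 over all). NM_001159517.1 had 84.4 CPM in WT and 73.3 CPM in VLDLR_KO and was not called (-0.22, adjusted p = 0.608 over the transcripts of the key genes, 0.827 over all). Both called transcripts were also lower than in ROBO4_KO, by -1.20 and -0.75 (adjusted p = 0.00231 and 6.59e-05 over the transcripts of the key genes, 0.0305 and 0.00128 over all). Of the 10 tested transcripts of the key genes 2 were called in these comparisons. None, 0 of 10, was called in ROBO4_KO against WT by edgeR.

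Slc17a5, which encodes the lysosomal sialic acid exporter sialin (Entrez 235504, chromosome 9, 78536487 to 78588045), was not called in any of the 3 comparisons. VLDLR_KO differed from WT by -0.12 (adjusted p = 0.624), ROBO4_KO from WT by 0.11 (adjusted p = 1) and VLDLR_KO from ROBO4_KO by -0.23 (adjusted p = 0.338). Its transcript NM_172773.3 had 87.9 CPM in WT and 82.3 CPM in VLDLR_KO (log2 fold change -0.09, adjusted p = 0.832 over the transcripts of the key genes, 0.957 over all). Within the forms Slc17a5 had 105 ± 1.91 CPM (n = 3) and 84.9 ± 5.39 CPM (n = 2) in WT, and 104 ± 12.1 CPM (n = 2) and 78.9 ± 6.1 CPM (n = 3) in VLDLR_KO, and the differences of VLDLR_KO from WT were -0.005 and -0.11 (adjusted p = 0.974 and 0.483). With the code form as a covariate, VLDLR_KO and ROBO4_KO differed by -0.23 at an adjusted p of 0.0416, the lowest over the alternatives (0.0416 to 0.598). Circular RNAs were not analysed here.

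**Figure D2:**
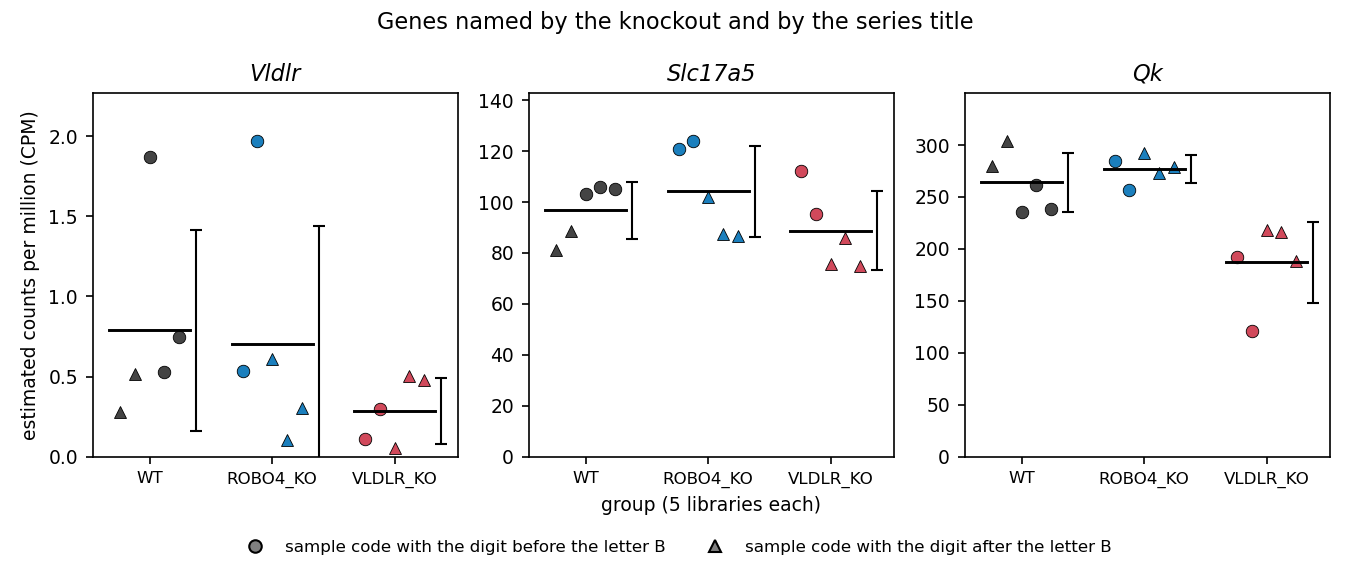
CPM of Vldlr, Slc17a5 and Qk in each of the 15 libraries by genotype; lines are group means, bars are SD (cut at 0), circles are codes with the digit before B and triangles codes with the digit after B. Qk averages 264 CPM in WT, 277 CPM in ROBO4_KO and 187 CPM in VLDLR_KO, and Vldlr is near 0 in most libraries.

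The comparison of VLDLR_KO with WT asked what loss of the VLDL receptor changes in macrophages. The largest losses included Npy, the neuropeptide Y gene, which had 186 ± 75.9 CPM in WT and 1 count in all VLDLR_KO libraries together, a ratio of 17200 (counting interval 3090 to 680000). Rab6b, a Golgi trafficking GTPase, fell from 24.4 ± 5.73 to 0.0649 ± 0.118 CPM (log2 fold change -8.39, SE 0.56, adjusted p = 1.59e-07), and Rnaset2b, a lysosomal ribonuclease, from 53.1 ± 3.6 to 0.313 ± 0.371 CPM (-7.39, SE 0.46, adjusted p = 1.03e-07). Among the gains, the chemokine gene Cxcl14 rose from 9.57 ± 5.15 to 145 ± 26.8 CPM (3.92, SE 0.40, adjusted p = 1.16e-05), and Gdpd3, a lysophospholipase D gene, from 0.425 ± 0.147 to 99.8 ± 66.5 CPM (7.86, SE 0.50, adjusted p = 1.24e-07). Eno1b, a near-identical copy of the enolase gene Eno1, had 0 counts in WT and ROBO4_KO and 274 ± 41.9 CPM in VLDLR_KO, at least 1690-fold higher than in WT.

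In all, 1086 of 11668 genes (9.31%) differed between VLDLR_KO and WT, 454 higher and 632 lower, and 2839 had an unadjusted p under 0.05. Of the calls 177 were at least 2-fold higher and 276 at least 2-fold lower. Groups did not overlap for 855 of the called genes and for 1100 of all genes (9.43%, against 0.79% by chance). Within the code forms 2442 genes (1190 higher, 1252 lower) and 1839 genes (791 higher, 1048 lower) were called, and 1082 of the 1086 pooled calls (99.6%) had the same sign in both. The pooled calls came from the same libraries, which favours such agreement. Over all genes the log2 fold changes in the forms had r = 0.452 (across genes, which are not independent replicates). Other large losses were those of C77080 (289 to 0.737 CPM, log2 fold change -8.60) and of Trim30d (-6.74) and Trim12a (-6.46), genes of the antiviral TRIM family. Further gains were Ifi202b, an interferon-inducible gene (0 in WT, 12.8 ± 3.53 CPM in VLDLR_KO, at least 78.8-fold), Angptl7 (7.12), Tdg-ps (5.53), Plekha7 (5.09), Rims2 (4.66), Amd2 (0.801 to 12.9 CPM) and Stard13 (3.97), all with adjusted p of at most 0.00725. Reads of near-identical copies cannot be assigned with certainty. Sums of a gene and a copy were made only for a few chosen pairs. For the other genes and transcripts, such as Rnaset2b and Rps6, shared reads were not checked. The sum of Eno1 and Eno1b rose by only 0.42 (SE 0.10) on the log2 scale, while Eno1 alone fell from 436 to 314 CPM. The sums of Amd1 and Amd2 (0.02, SE 0.19) and of Tdg and Tdg-ps (0.15, SE 0.21) changed by less than their SE, so the gains of Amd2 and Tdg-ps are uncertain.

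**Figure D3:**
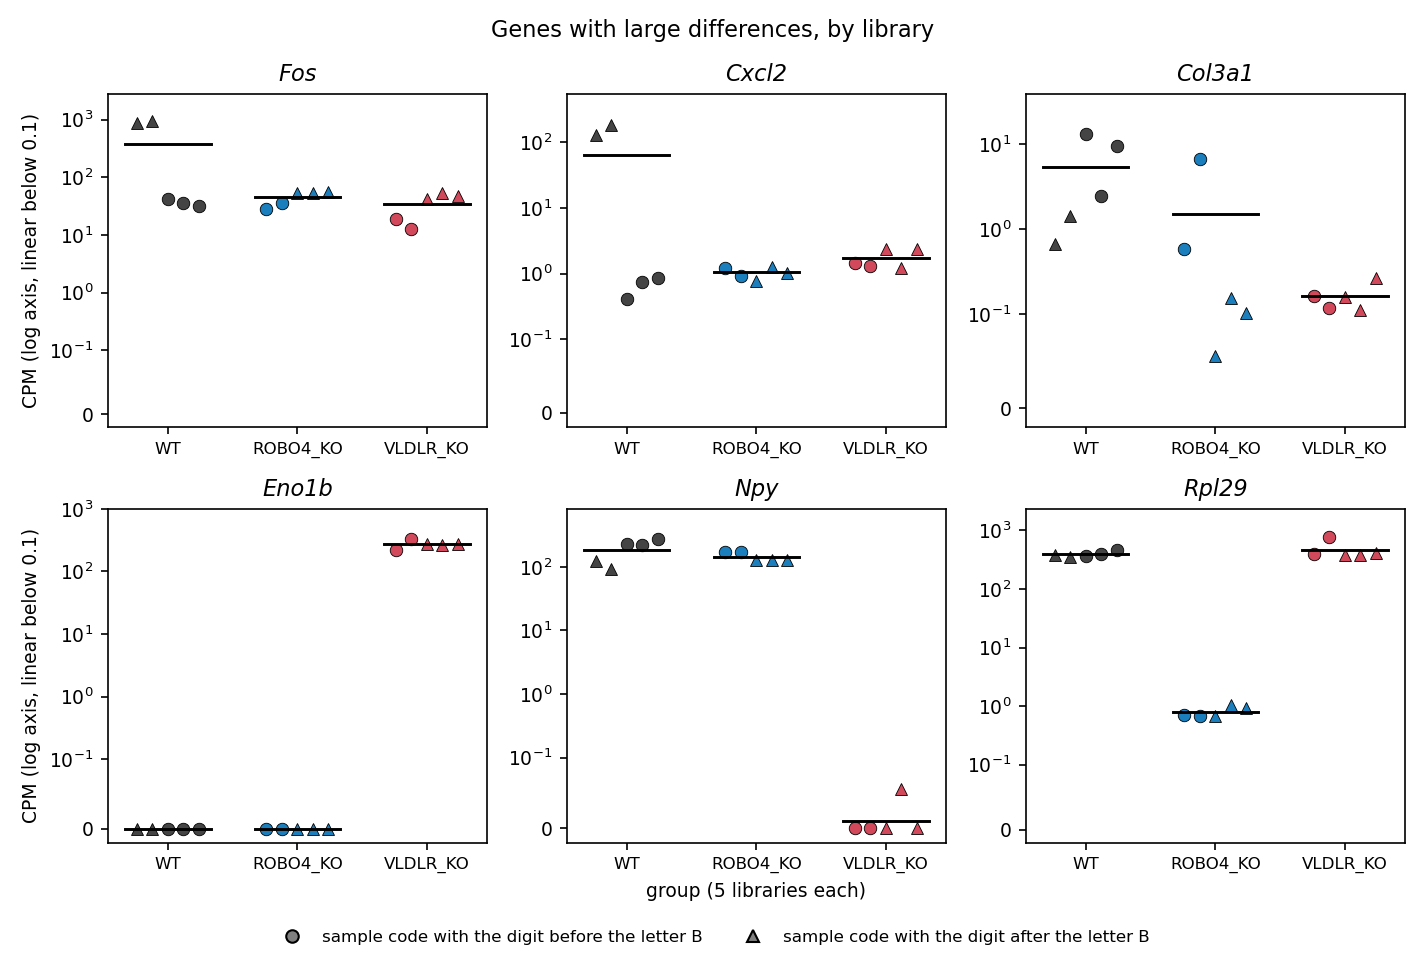
CPM of Fos, Cxcl2, Col3a1, Eno1b, Npy and Rpl29 in each library by genotype, on a log axis that is linear below 0.1; lines are group means and symbols give the code form. Npy is near 0 in VLDLR_KO, Eno1b is at 0 in the other groups, Rpl29 averages 0.799 CPM in ROBO4_KO, and Fos and Cxcl2 are high in 2 of the 5 WT libraries.

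Genes of interferon defence were lower as a group in VLDLR_KO than in WT, and those of cholesterol synthesis in VLDLR_KO replicates 1 and 2. Of 27 interferon genes 23 were lower (median log2 fold change -0.36, camera adjusted p = 0.000513, adjusted p = 0.643 with an estimated correlation), with 5 called lower, and 7 adjusted over the list alone. The level of the interferon list also followed the code form. With the digit before B it was 0.44 to 0.99 in WT and 0.24 and 0.41 in VLDLR_KO. With the digit after B it was -0.12 and 0.02 in WT and -0.64 to -0.26 in VLDLR_KO. Rsad2, the antiviral enzyme viperin, fell from 33.4 ± 16.7 to 6.75 ± 0.853 CPM (-2.30, SE 0.30, adjusted p = 0.000163), by -2.60 and -1.41 within the forms, and Cmpk2 (-1.19) and Oasl2 (-1.13) fell with it. Trim30a (-0.48, adjusted p = 0.0238) lost its call without WT replicate 4 (0.0557) or WT replicate 5 (0.0599). Of 28 cholesterol synthesis genes 23 were lower (median -0.35, camera adjusted p = 0.000389, adjusted p = 0.643 with an estimated correlation), and 4 were called lower, also 4 adjusted over the list alone. The level of this list was -0.98 and -1 in VLDLR_KO replicates 1 and 2, both with the digit before B. It was 0.11 to 0.27 in the other VLDLR_KO libraries and 0 to 0.35 in WT. Without these 2 libraries its median on the voom scale moved from -0.399 to -0.063 (adjusted p = 0.578; range over the alternatives 4.58e-06 to 0.643). Insig1, a regulator of sterol sensing, fell from 145 ± 15.4 to 83.8 ± 16.6 CPM (-0.80, SE 0.17, adjusted p = 0.00746), by -1.16 and -0.50 within the forms, and the sterol desaturase gene Sc5d fell from 96.1 ± 12.7 to 51.3 ± 15.8 CPM (-0.90, SE 0.20, adjusted p = 0.00874), by -1.55 and -0.45. The synthase gene Hmgcs1 (-0.75, adjusted p = 0.0277; -1.39 and -0.40 within the forms) lost its call without WT replicates 2, 3 or 4 or VLDLR_KO replicate 1 (adjusted p = 0.0542 to 0.0699).

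Antigen presentation and matrix genes were also lower in VLDLR_KO. All 8 tested MHC class II genes were lower (median -0.68, camera adjusted p = 0.00629, adjusted p = 0.643 with an estimated correlation), with 2 called lower and 5 adjusted over the list alone, and this list lost its call without WT replicate 2 (0.0543). Its level was 0.61 and 1.03 in WT replicates 1 and 2, -0.17 to 0.03 in the other WT libraries and -0.7 to -0.08 in VLDLR_KO. Without both WT libraries its median on the voom scale moved from -0.618 to -0.278 (adjusted p = 0.251; range over the alternatives 0.000343 to 0.643). H2-Aa, an MHC class II chain, fell from 31.4 ± 10.2 to 14.9 ± 3.62 CPM (-1.08, SE 0.25, adjusted p = 0.0148), by -1.12 and -1.22 within the forms, and was not called without these WT libraries (-0.82, adjusted p = 0.0759; range 0.000887 to 0.0759). All 21 extracellular matrix and fibroblast genes were lower (median -2.59, camera adjusted p = 8.97e-06, adjusted p = 0.643 with an estimated correlation), with 1 called lower and 17 adjusted over the list alone. Single libraries stood apart. The level of this list was 2.89 in WT replicate 3 and -0.07 to 1.5 in the other WT libraries. It was -2.93 in VLDLR_KO replicate 1 and -0.91 to -0.28 in the other VLDLR_KO libraries. Osteoblast and stromal genes were at 1.55 in WT replicate 3 and -2.23 in VLDLR_KO replicate 1 as well. The called gene, Col3a1, a fibrillar collagen, had 5.49 ± 5.61 CPM in WT and 0.163 ± 0.0612 CPM in VLDLR_KO (-5.01, SE 1.30, adjusted p = 0.0248). It lost its call without WT replicate 3 (0.0597), VLDLR_KO replicate 3 (0.0562) or VLDLR_KO replicate 5 (0.0537). Col5a1 was not called (-3.18, adjusted p = 0.0571).

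Immediate-early genes, which respond within minutes to stimuli, were high in 2 WT libraries. Of 20 such genes 19 were lower in VLDLR_KO than in WT (median -1.41, camera adjusted p = 0.00629, adjusted p = 0.658 with an estimated correlation), with 6 called lower and 9 adjusted over the list alone. The list lost its call without WT replicate 1 (0.0631) or WT replicate 2 (0.0969), and on the voom scale its median moved from -0.79 with all libraries to -0.006 without both (adjusted p = 0.905; range over the alternatives 3.19e-06 to 0.905). Fos, a subunit of the AP-1 transcription factor, had 900 ± 63.1 CPM in these 2 libraries and 36.8 ± 5.17 CPM in the other 3 WT libraries, against 34.9 ± 18.1 CPM in VLDLR_KO (n = 5), and within the forms it differed from WT by -4.24 (digit after B, adjusted p = 4.58e-07) and -1.22 (digit before B, adjusted p = 0.0109). The pooled log2 fold changes were -3.45 for Fos (adjusted p = 0.0296), -5.91 for Fosb (adjusted p = 0.0216), -3.69 for Nr4a1 (adjusted p = 0.0175) and -2.43 for Zfp36 (adjusted p = 0.0158). The chemokine gene Cxcl2 had 62.4 ± 86.6 CPM in WT and 1.74 ± 0.566 CPM in VLDLR_KO (-5.15, adjusted p = 0.0293), but within the form with the digit before B it differed by 1.05 (adjusted p = 0.11). Fos was lost without WT replicates 1 or 2 or VLDLR_KO replicates 1, 2, 3 or 5 (adjusted p = 0.0541 to 0.0742), Fosb without WT replicate 2 (0.0506) or VLDLR_KO replicate 5 (0.0509), and Cxcl2 without WT replicates 1 or 2 or any VLDLR_KO replicate (0.052 to 0.0697).

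Macrophage identity genes did not pass the test as a group in VLDLR_KO, with 11 of 22 genes higher (median -0.02, camera adjusted p = 0.813), while single members changed. The lysozyme gene Lyz2 rose from 7510 ± 2720 to 18000 ± 5430 CPM (1.26, SE 0.25, adjusted p = 0.00473), by 2.08 and 0.46 within the forms, and this was the 1 member called higher of 22. Of the 3 called lower, Fcgr1, the high-affinity IgG receptor, had a log2 fold change of -0.84 (adjusted p = 0.0168) and Adgre1, the F4/80 antigen, of -0.36 (adjusted p = 0.0176, lost without VLDLR_KO replicate 5 at 0.053). Adjusted over the list alone, 3 were higher and 3 lower. Alternative activation genes went both ways, with 2 called higher and 2 lower of 16 (3 and 2 adjusted over the list alone, camera adjusted p = 0.353): Mgl2 rose by 3.64 (adjusted p = 0.00135), the scavenger receptor gene Cd163 by 2.11 (adjusted p = 0.00514), and the cytokine gene Il10 fell by 4.22 (adjusted p = 0.0173). Mgl2 and Cd163 had low levels, with 0.156 and 0.867 CPM in WT and 1.98 and 3.75 CPM in VLDLR_KO. Il10 was high in WT replicates 1 and 2 alone (10.2 and 10.6 CPM, against 0.312 to 0.741 CPM in the other WT libraries and 0.119 to 0.502 CPM in VLDLR_KO). Without them it differed by -1.07 (adjusted p = 0.356; range over the alternatives 0.000113 to 0.356). Inflammatory cytokines had 3 called higher and 3 lower of 21 (3 and 4 adjusted over the list alone, camera adjusted p = 0.692), among them Saa3 (2.71, adjusted p = 0.0145), the inflammasome gene Nlrp3 (0.99, adjusted p = 0.0166), Il18 (0.58, adjusted p = 0.0168) and Ptgs2 (-4.68, adjusted p = 0.00977). Ptgs2 had 38.2 and 52.7 CPM in WT replicates 1 and 2, 3.09 to 4.63 CPM in the other WT libraries and 0.476 to 1.22 CPM in VLDLR_KO. Without these 2 WT libraries it differed by -2.22 (adjusted p = 0.108; range 1.47e-06 to 0.134). Saa3 differed by 3.71 (adjusted p = 0.00444) in the form with the digit before B and by 1.16 (adjusted p = 0.113) in the other. Its pooled levels were low, at 0.369 CPM in WT and 2.46 CPM in VLDLR_KO.

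Angiogenic factors gave no call in VLDLR_KO against WT: 0 of 27 were called by edgeR, also 0 adjusted over the list alone, and 17 were lower (camera adjusted p = 0.23). Antiangiogenic factors had 1 member called higher and 2 lower of 12 (1 and 4 adjusted over the list alone, camera adjusted p = 0.0725). Col18a1, the collagen from which endostatin is cut, fell from 22.3 ± 12 to 2.55 ± 1.1 CPM (-3.12, SE 0.42, adjusted p = 0.000179), by -3.93 and -1.70 within the forms. The level of the antiangiogenic list was highest in WT replicate 3 (1.4) and ROBO4_KO replicate 2 (1.29) and lowest in VLDLR_KO replicate 1 (-1.22). Extracellular matrix and fibroblast genes, a list without members in common, were also highest (2.89 and 2.79) and lowest (-2.93) in these libraries. Slit and Robo signalling had 6 members called lower and 0 higher of 26 (6 adjusted over the list alone, camera adjusted p = 0.0725, 0.643 with an estimated correlation, fry adjusted p = 0.00952). The level of the Slit and Robo list was also highest in WT replicate 3 (0.59) and ROBO4_KO replicate 2 (0.45). It was 0.09 to 0.31 in the other WT libraries, -0.08 to 0.1 in the other ROBO4_KO libraries and -0.53 to -0.16 in VLDLR_KO. Its adaptor gene Nck2 fell from 21.4 ± 1.36 to 7.57 ± 1.33 CPM (SE of the log2 fold change 0.12, adjusted p = 1.14e-06), with log2 fold changes of -2.87 for the netrin receptor gene Unc5a (adjusted p = 0.000389), -2.71 for Slit1 (adjusted p = 0.0102) and -2.75 for Srgap1 (adjusted p = 0.0116). Unc5a, Slit1 and Srgap1 had low levels, with 1.56, 4.26 and 0.776 CPM in WT and 0.207, 0.652 and 0.109 CPM in VLDLR_KO. Among lipoprotein receptors and efflux genes, with 1 called higher and 3 lower of 30 (2 and 3 adjusted over the list alone, camera adjusted p = 0.277), the lipid droplet gene Plin2 fell from 1180 ± 74 to 646 ± 126 CPM (-0.86, SE 0.13, adjusted p = 0.000405), by -0.95 and -0.77 within the forms. The receptor chaperone gene Lrpap1 rose from 139 ± 6.4 to 206 ± 23.3 CPM (0.56, SE 0.09, adjusted p = 0.000963), and Lrp12 fell by 1.06 (adjusted p = 0.015).

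Lysosomal genes as a group did not pass the test (camera adjusted p = 0.185), but 3 of 42 were called lower and 0 higher (also 3 adjusted over the list alone). They were the beta-galactosidase gene Glb1 (119 ± 10.4 to 58.9 ± 15.2 CPM, -1.02, SE 0.14, adjusted p = 0.000167; -0.61 and -1.39 within the forms), the cathepsin gene Ctsh (268 ± 69.5 to 94.9 ± 27.7 CPM, adjusted p = 0.00093) and the galactosylceramidase gene Galc (-0.71, adjusted p = 0.00511). Complement genes had 5 called higher and 1 lower of 18 (5 and 3 adjusted over the list alone, camera adjusted p = 0.382), with the complement inhibitor gene Cd59a up by 0.88 (adjusted p = 0.00227), the receptor gene C5ar2 up by 0.67 (adjusted p = 0.0119) and the receptor gene C3ar1 at -0.59 (adjusted p = 0.00575). The other lists passed no camera test. RNA-binding proteins of circular RNA formation had 3 called higher and Qk lower of 33 (5 and 1 adjusted over the list alone, camera adjusted p = 0.252). Wnt signalling had 1 higher (Ctnnb1, beta-catenin, 0.50, adjusted p = 0.0109) and 1 lower of 24 (1 and 1 adjusted over the list alone, camera adjusted p = 0.93), hypoxia and glycolysis 2 lower of 30 (2 adjusted over the list alone, 0.711), and endoplasmic reticulum and oxidative stress 1 higher and 3 lower of 25 (1 and 3 adjusted over the list alone, 0.353). The lower hypoxia and glycolysis genes include Eno1, whose sum with its copy Eno1b rose (0.42, SE 0.10). The osteoclast list had 2 lower of 19 (1 higher and 3 lower adjusted over the list alone, 0.673), endothelium 1 lower of 5 (1 adjusted over the list alone, 0.655), and osteoblasts and stroma 0 of 5 (2 adjusted over the list alone, 0.353). Cell cycle genes had 0 of 40 called with 37 higher (0 adjusted over the list alone, 0.353). Their level followed the code form, at -1.45 and -1.68 in VLDLR_KO and -0.55 to -0.5 in WT with the digit before B, and 0.5 to 1.43 and 0.2 to 0.57 with the digit after B. With the form as a covariate their median on the voom scale moved from 0.196 to 0.047. Neutrophil markers had 0 of 8 called (0 adjusted over the list alone, 0.606, median -0.36 although camera gave the direction up), and dendritic cell markers 0 of 9 (0 adjusted over the list alone, 0.692).

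**Figure D4:**
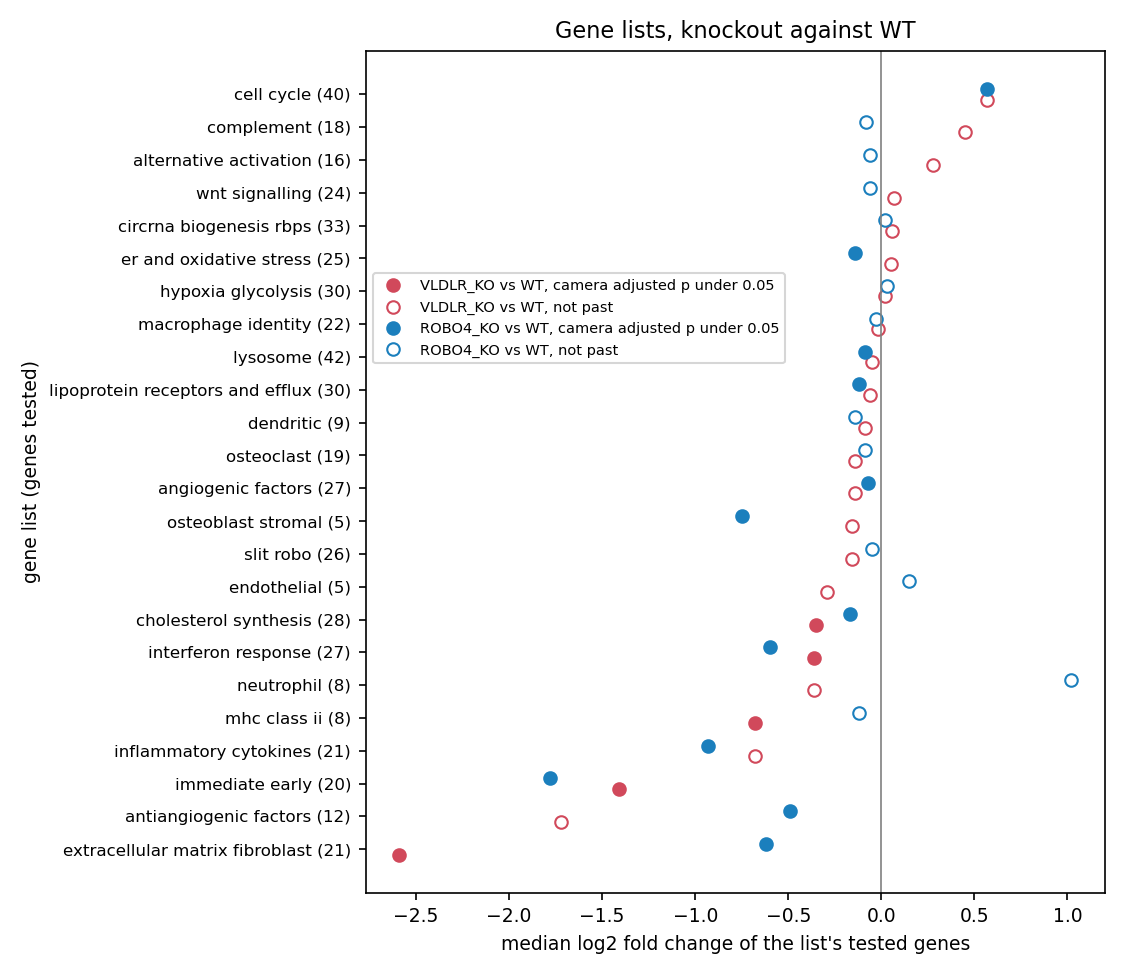
Median log2 fold change of each fixed gene list in VLDLR_KO against WT and ROBO4_KO against WT; filled symbols have a camera adjusted p under 0.05 with the preset correlation. Extracellular matrix genes reach -2.59 in VLDLR_KO, and interferon genes lie at -0.36 in VLDLR_KO and -0.60 in ROBO4_KO.

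Annotation terms and transcripts gave further detail on VLDLR_KO against WT. Among genes called higher, 7 of 25 genes of negative regulation of mRNA splicing via the spliceosome were found where 0.945 were expected (one-sided Fisher's exact test, adjusted p = 0.0307), namely Hnrnpl, Rbm10, Rbmxl1, Rnps1, Srsf4, Srsf9 and U2af2. The gene calls of Hnrnpl and U2af2 were lost in 5 and 12 of the fits without 1 library (adjusted p = 0.0593 to 0.0905 and 0.0519 to 0.118). DNA integration, with 8 of 23 genes and 0.869 expected (adjusted p = 0.00255), consisted of unnamed predicted genes. No term, 0 of 2206, passed for genes called lower (smallest adjusted p = 0.135). Of 30096 transcripts 646 were called (226 higher, 420 lower). The RNA-editing enzyme gene Apobec1 gained NM_031159.3 (log2 fold change 4.28), and NM_001111279.1 of Wdfy1 (2.20), NM_207675.2 of Cadm1 (2.85) and NM_024228.2 of Gdpd3 (7.84) were also higher. Lower were NM_001285867.1 of C77080 (-6.85), XM_006510113.3 of St3gal4 (-9.89), NM_001080941.1 of Zfp429 (-4.58), NM_009096.3 of Rps6 (-2.43) and the Npy transcript. Of 1666 noncoding transcripts 13 were called.

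The comparison of ROBO4_KO with WT asked what loss of the guidance receptor changes. Rpl29, a ribosomal protein gene, fell from 394 ± 39.5 to 0.799 ± 0.172 CPM (log2 fold change -8.93, SE 0.27, adjusted p = 4.13e-11), by -9.22 and -8.70 within the forms, and had 471 ± 173 CPM in VLDLR_KO. Its predicted copy Gm8210 rose from 0.0752 to 329 CPM, and the sum of both fell by only 0.25 (SE 0.07). Reads of such copies cannot be assigned with certainty, so a loss of Rpl29 mRNA is uncertain. The adhesion gene Cadm1 rose from 140 ± 30.2 to 610 ± 137 CPM (2.12, SE 0.19, adjusted p = 2.54e-05) and was also high in VLDLR_KO (477 ± 98.7 CPM). Nnt, the mitochondrial transhydrogenase gene that is partly deleted in C57BL6J mice (Entrez 18115, chromosome 13, 119335527 to 119429801), rose from 26.1 ± 2.48 to 53 ± 5.92 CPM (1.02, SE 0.11, adjusted p = 0.000265), by 1.08 and 0.91 within the forms, and had 54.6 ± 7.88 CPM in VLDLR_KO. The respiratory chain gene Cox7a2 fell from 53.5 ± 10.7 to 12.5 ± 1.07 CPM (-2.09, SE 0.22, adjusted p = 0.000217).

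In all, 39 genes (0.334%) differed between ROBO4_KO and WT, 20 higher and 19 lower, and 440 had an unadjusted p under 0.05. With limma-trend on FPKM the split was 21 higher and 10 lower. Groups did not overlap for 38 of the called genes and for 256 of all genes (2.19%, against 0.79% by chance). Within the forms 20 genes (11 higher and 9 lower, digit before B) and 188 genes (37 higher and 151 lower, digit after B) were called. All 39 pooled calls had the same sign in both forms, but they came from the same libraries, which favours such agreement. Over all genes the log2 fold changes in the forms had r = 0.372. Further genes called higher were Dynlt1b (1.74), Aph1b (14.7 to 41.6 CPM), Wdfy1 (1.38), Nxpe4 (1.36) and Cd59a (1.14), all with adjusted p of at most 0.00228. Lower were Lrmda (-3.75), Abhd14b (-1.59), Tmem254b (-1.04) and Zfp932 (-0.82), with adjusted p of at most 0.00512. Whether genes such as Dynlt1b and Tmem254b share reads with near-identical copies was not checked. Il18 (0.84, adjusted p = 0.0129) lost its call without ROBO4_KO replicate 4 (0.0504), and Spp1, the osteopontin gene (3700 ± 370 to 2210 ± 333 CPM, -0.75, adjusted p = 0.0322), lost it without WT replicates 1, 3, 4 or 5 or ROBO4_KO replicates 3, 4 or 5 (0.0711 to 0.108). Rsad2 (-1.51, adjusted p = 0.042) lost its call without any 1 library except WT replicates 1 and 2 (0.052 to 0.158).

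Interferon genes were lower in ROBO4_KO in every member. All 27 were lower than in WT (median -0.60, camera adjusted p = 9.46e-16, adjusted p = 0.217 with an estimated correlation), with 1 called lower (Rsad2) and 10 adjusted over the list alone, and Zbp1 was not called (-1.15, adjusted p = 0.288). By camera with the preset correlation 12 lists passed, 11 of them lower, and by an estimated correlation or fry 0 passed. Inflammatory cytokines were lower in 19 of 21 (median -0.93, camera adjusted p = 4.98e-05, 0.244 with an estimated correlation), with Il18 called higher, and 1 higher and 8 lower adjusted over the list alone. Immediate-early genes were lower in 18 of 20 (median -1.78, camera adjusted p = 1.56e-08, 0.244 with an estimated correlation), with 0 called by edgeR and 13 adjusted over the list alone. Without WT replicates 1 and 2 the median of immediate-early genes on the voom scale moved from -1.22 to -0.03 (adjusted p = 0.719; range over the alternatives 6.04e-23 to 0.719). In the same alternative inflammatory cytokines had an adjusted p of 0.236 (range 6.31e-09 to 0.318) and interferon genes one of 4.36e-19 (range 2.38e-19 to 0.288). Fosb (-6.26, adjusted p = 0.19) and Nr4a1 (-3.58, adjusted p = 0.207) were not called, and Fosb differed by 0.44 within the form with the digit before B. Extracellular matrix genes were lower in 18 of 21 (median -0.62, camera adjusted p = 2.55e-09, 0.244 with an estimated correlation) with 0 called, also 0 adjusted over the list alone; Col6a1 (-1.61) and Col3a1 (-1.84) had adjusted p of 1. The level of this list was 2.79 in ROBO4_KO replicate 2 and -1.16 to -0.21 in the other ROBO4_KO libraries, and 2.89 in WT replicate 3. Over the alternatives its median on the voom scale ranged from -2.054 to -0.838, against -1.275 with all libraries.

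Further lists passed camera in ROBO4_KO with the preset correlation, and their calls all ended with an estimated one. Cholesterol synthesis (median -0.17, adjusted p = 0.00026, 0.454 with an estimated correlation), lysosome (-0.09, 0.00122, 0.333 with an estimated correlation) and endoplasmic reticulum and oxidative stress (-0.14, 0.00177, 0.217 with an estimated correlation) had 0 called members, and 0, 0 and 1 adjusted over the list alone. Antiangiogenic factors had a median of -0.49 (adjusted p = 0.00587, 0.244 with an estimated correlation, 0 of 12 called), and lost the call without ROBO4_KO replicate 4 (0.0655) or ROBO4_KO replicate 5 (0.0531). Angiogenic factors (-0.07, adjusted p = 0.0326, 0.217 with an estimated correlation) lost it without WT replicates 2 or 3, ROBO4_KO replicates 1, 4 or 5 or VLDLR_KO replicate 2 (0.0542 to 0.117). Osteoblast and stromal genes (-0.75, adjusted p = 0.0326, 0.244 with an estimated correlation) lost it without WT replicate 3, ROBO4_KO replicates 1 or 4 or VLDLR_KO replicate 2 (0.0551 to 0.0757), and each of these lists had Spp1 as its 1 called gene. Lipoprotein receptors and efflux (-0.12, adjusted p = 0.0438, 0.244 with an estimated correlation, 0 of 30 called) lost it without WT replicates 1 or 2 or ROBO4_KO replicates 1, 2, 4 or 5 (0.0551 to 0.205). Cell cycle genes were higher in 40 of 40 (median 0.57, adjusted p = 0.0179, 0.744 with an estimated correlation, 0 called), but lost the call without WT replicates 3, 4 or 5 or ROBO4_KO replicates 4 or 5 (0.0794 to 0.879), and on the voom scale their median moved from 0.31 to 0.05 with the code form as a covariate.

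Genes near Robo4 on chromosome 9 were called in ROBO4_KO more often than elsewhere. Within 10 Mb of Robo4, 6 of 84 tested genes were called where 0.281 were expected (two-sided Fisher's exact test, odds ratio 26.8, p = 3.18e-07). Chromosome 9 held 17 of the 39 calls (43.6%) and 5.56% of the tested genes (exact test, adjusted p = 1.27e-10), between 36.8 and 106.4 Mb. They include the adhesion genes Cadm1 and Mcam (1.93), the cytokine gene Il18, the secretase subunit gene Aph1b, Cox7a2, the actin-binding gene Tpm1 (-0.69) and Rpl29. In VLDLR_KO against WT 10 of 71 genes within 10 Mb of Vldlr were called where 6.56 were expected (exact test, p = 0.151). Genes of chromosome 9 other than those of the rule were chosen after their values were seen.

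**Figure D5:**
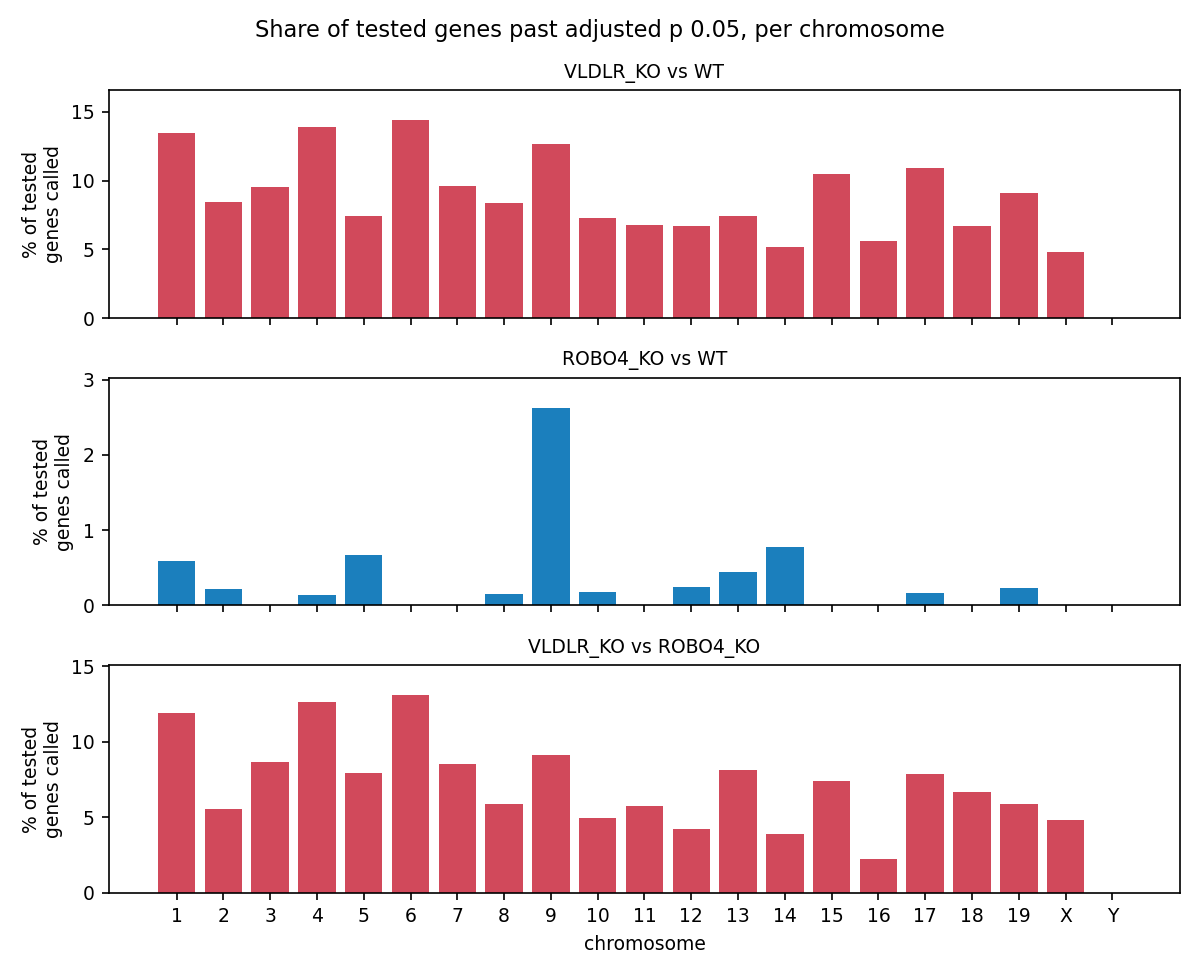
Percent of tested genes called on each chromosome in VLDLR_KO against WT, ROBO4_KO against WT and VLDLR_KO against ROBO4_KO, both directions together, each with its own vertical scale. Chromosome 9 holds 17 of the 39 calls in ROBO4_KO.

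Both knockouts shared 26 calls against WT. Of these 18 genes were higher in both and 8 lower in both, with 0 in opposite directions, where independent lists would share 0.778 and 1.03. Shared genes included Cadm1 (log2 fold change 1.77 in VLDLR_KO and 2.12 in ROBO4_KO), Nnt (1.06 and 1.02), Dynlt1b (2.02 and 1.74), Mcam (2.26 and 1.93), Cox7a2 (-1.94 and -2.09), Rsad2 and Cd59a, and 10 of the 26 lie on chromosome 9. Log2 fold changes over all genes had r = 0.412 (across genes, which are not independent replicates) and a covariance of 0.1337. Simulated groups without effects that shared the WT libraries gave r = 0.504, a covariance of 0.0523 and 0 shared calls. The simulation held no code form, although WT had 3 and each knockout 2 libraries with the digit before B. The form can thus add to the observed covariance, so the simulated value cannot serve as its chance level. When the WT libraries were split between the comparisons, 3 to 9 calls were shared (median 6). There r was -0.124 to 0.379 and the median covariance 0.0972, and the form can add to these too.

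The direct comparison of the knockouts asked whether their effects differ. Npy had 145 ± 22.8 CPM in ROBO4_KO against 1 count in VLDLR_KO (ratio 13400, counting interval 2400 to 528000), and Rab6b (-8.33), C77080 (-8.21), Rnaset2b (-7.27), Trim30d (-6.62) and Trim12a (-6.40) were lower in VLDLR_KO as they were against WT. Angptl7 (6.77), Plekha7 (5.59), Stard13 (5.03) and Ptprd (4.68) were higher in VLDLR_KO. So were Rpl29 (9.19), with its copy Gm8210 lower (-11.46), and Tdg-ps (4.62), but both are uncertain because of their near-identical copies. Lower were also the adenylate cyclase gene Adcy2 (-5.62), Zfp984 (-4.62), Zfp429 (-4.47) and the ATP synthase subunit gene Atp5e (31.4 ± 2.39 to 1.68 ± 1.19 CPM, -4.23, SE 0.33, adjusted p = 8.18e-07). In all 888 genes differed (7.61%, with 382 higher and 506 lower in VLDLR_KO), and 2661 had an unadjusted p under 0.05. Of the 888, 887 had the same sign in both forms, but they came from the same libraries, which favours such agreement. Over all genes the log2 fold changes in the forms had r = 0.509. Within the forms 1500 genes (695 higher, 805 lower) and 1741 genes (847 higher, 894 lower) were called, and groups did not overlap for 979 genes (8.39%, against 0.79% by chance).

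List members called between the knockouts included many that also differed between VLDLR_KO and WT. Lyz2 was higher in VLDLR_KO (1.21, adjusted p = 0.00719) and Adgre1 lower (-0.45, adjusted p = 0.00535), Saa3 (3.02, adjusted p = 0.0091), Nlrp3 (1.04, adjusted p = 0.0141) and Mgl2 (2.93, adjusted p = 0.00479) were higher, and Plin2 (-0.71, adjusted p = 0.0024), Glb1 (-0.93, adjusted p = 0.000426), Ctsh (-1.35, adjusted p = 0.00226), Nck2 (-1.30, adjusted p = 4.76e-06) and Col18a1 (-2.59, adjusted p = 0.000912) were lower. Of genes of hypoxia and glycolysis 3 were higher and 3 lower of 30 (5 and 3 adjusted over the list alone), with Eno1 (-0.58, adjusted p = 0.00233), the aldolase gene Aldoc (-1.08, adjusted p = 0.00871) and the glucose transporter gene Slc2a1 (0.41, adjusted p = 0.00981). The copy Eno1b had 0 CPM in ROBO4_KO and 274 CPM in VLDLR_KO, so a lower level of Eno1 is uncertain. Spp1 was higher (0.58, adjusted p = 0.0183) and Eng, a TGF-beta co-receptor, lower (-0.62, adjusted p = 0.00605). Among lists 0 of 24 passed camera, with the smallest adjusted p of 0.0697 for MHC class II genes, 0 passed fry, and 8 passed the fry test for changes in either direction. H2-Aa (-0.74, adjusted p = 0.0936), H2-Eb1 (-0.86, adjusted p = 0.109), Hmgcs1 (-0.58, adjusted p = 0.0919), Cyp51 (-0.67, adjusted p = 0.153), Fbn1 (-3.19, adjusted p = 0.0873) and Mgp (-4.75, adjusted p = 0.0888) were not called. The apolipoprotein gene Apoe, at 4480 ± 716 CPM in ROBO4_KO and 11000 ± 8540 CPM in VLDLR_KO (1.30, adjusted p = 0.0475), was called, but lost the call without any 1 library except VLDLR_KO replicates 3, 4 and 5 (0.0591 to 0.106). Median and camera direction differed for the neutrophil (-1.02, up), osteoblast and stromal (-0.74, up), lipoprotein (0.09, down), lysosome (0.05, down) and endothelium (0.08, down) lists.

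Transcripts called numbered 26 in ROBO4_KO against WT (14 higher, 12 lower) and 584 between the knockouts (198 higher, 386 lower). In ROBO4_KO the estimated counts of both Rpl29 transcripts were lower (NM_001324533.1 at -9.18 and NM_009082.3 at -11.53). XM_985134.6 of the copy Gm8210 was higher (11.97), so a loss of Rpl29 transcripts is uncertain. NM_028275.1 of Lrmda (-3.86), NM_009945.3 of Cox7a2 (-2.08) and NM_001205072.1 of Josd2 (-7.81) were also lower, while NM_177583.4 of Aph1b rose (1.71). Between the knockouts Apobec1 (4.31) and NM_010395.7 of H2-T10 (3.26) were higher in VLDLR_KO, and the transcripts of St3gal4 (-9.62) and Rps6 (-2.51) lower. In the authors' deposited table the genes with q under 0.05 numbered 2326 and 1903 for VLDLR_KO against WT in the forms with the digit before and after B, 219 and 359 for ROBO4_KO against WT, and 970 and 1595 between the knockouts.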

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

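The tests of the 100 groupings of libraries, of near-identical copies and of neutrophils were planned before their results were seen, and the other tests below were chosen only afterwards.

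Genes called in ROBO4_KO against WT gathered on chromosome 9 (17 of 39), among them Rpl29, Cadm1 and Cox7a2. The code forms of the libraries are argued against, since with the form as a covariate, which raised the calls from 39 to 75, all 17 were still called, and 27 of the 75 lie on chromosome 9. Within the forms fewer libraries enter, and 4 of the 17 were called with the digit before B (4 of 20 calls on chromosome 9, exact test p = 0.0227) and 15 with the digit after B (32 of 188, p = 1.16e-08). Of the 17, 10 were also called in VLDLR_KO against WT. When the WT libraries were split so that the comparisons shared none, 33.3% to 71.4% of the chromosome 9 genes called in ROBO4_KO moved the same way in VLDLR_KO (unadjusted p under 0.05), against 6.9% to 12.5% of the other genes of this chromosome. Each of the higher percents rests on only 4 to 15 genes. Called genes can also reach a small p more easily than the others, which can add to the gap. Within these limits the gap argues against both a segment of another strain carried by ROBO4_KO alone and loss of ROBO4 alone as the cause of all of these calls. A difference in background between WT and both knockouts stays open, as it was not tested. Nnt, which is partly deleted in C57BL6J mice, bears on it. Its level was above WT by 1.06 in VLDLR_KO and 1.02 in ROBO4_KO, with 0.04 between the knockouts (edgeR adjusted p = 0.86), but 1 gene does not decide. Of the other 7 (Abhd14a, Abhd14b, Rpl29, Pcsk7, Gramd1b, Dusp7 and LOC102638888), 2 lie within 10 Mb of Robo4, and Abhd14a, Abhd14b, Rpl29 and Dusp7 lie at 106.4 Mb, with genes that both knockouts share in between. For these 7 a segment of another strain carried by ROBO4_KO alone and loss of ROBO4 cannot be told apart, since ROBO4_KO would carry both. Robo4 itself had at most 4 counts in a WT library, too few to weigh them. For Rpl29, reads shared with its copy Gm8210 stay open as well, since the sum of both fell by only 0.25 (SE 0.07).

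Several genes were near 0 in VLDLR_KO and expressed in WT, or the reverse: 24 passed limits of at most 0.5 and at least 5 CPM, 14 higher and 10 lower, such as Npy, Rab6b, Eno1b and Trim30d. A segment of another strain that flanks Vldlr is argued against, since 1 of the 22 placed genes lies on chromosome 19. Some of the 24 genes, picked out after their values were seen, were expressed in ROBO4_KO too. The predicted genes Gm42031, Gm41885, Gm41035 and Gm42102 had 28.1, 29.1, 6.57 and 6.59 CPM there. In WT they had 0, 0.169, 0.198 and 0.302 CPM. For these genes this argues against loss of VLDLR alone. For the others, alleles of another strain at many loci and an effect of VLDLR itself cannot be told apart here. Of the called genes 75.5% had another called gene within 1 Mb, above the mean of 1000 random sets (72.7%) and below their highest (77.1%), and 24 of the random sets were as high. Random sets came so close that this test can hardly decide. Calls were most frequent on chromosomes 6, 4, 1 and 9 (14.4%, 13.9%, 13.5% and 12.7% of tested genes, exact test, adjusted p of at most 0.0114). They were less frequent than elsewhere on 11, 14, 16 and X (6.75%, 5.17%, 5.63% and 4.83%, adjusted p of at most 0.0399). The cause of this uneven spread was not tested. Reads shared between near-identical copies stay open for these genes. Of the 24, 5 (Rab6b, Trim30d, Eno1b, Ifi202b and Trim12a) shared the stem of their name with a gene called in the opposite direction. Such a stem joins all members of broad families such as Rab or Trim, so this count does not measure near-identical copies. Eno1b, with Eno1 called lower, is such a copy, and unnamed copies would be missed.

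Immediate-early and inflammatory genes were high in WT replicates 1 and 2, with Tnf at 405 ± 53.2 CPM there and 33.5 CPM in the other WT libraries (Tnf was chosen after its values were seen). For immediate-early genes the code form alone is argued against, since their largest median difference between forms in a knockout was 0.34 on the log2 scale against 2.8 in WT. For inflammatory genes this median was 1.52 in WT, -0.66 in ROBO4_KO and -0.29 in VLDLR_KO. More neutrophils in these cultures than in all knockout cultures of this form are also argued against, but weakly. Of the ROBO4_KO libraries 2 had a higher level of neutrophil markers than both (2.08 and 1.68, against 1.67 and 1.61). ROBO4_KO replicate 3 (1.51) and the VLDLR_KO libraries of this form (0.6 to 1.05) were lower. The most abundant marker, Csf3r, had 67.7 CPM in WT and 48.8 CPM in ROBO4_KO, and Mmp9 19.4 and 44.2 CPM, and no sort or gate against neutrophils is named in the labels. Handling of the 2 cultures and a property of WT cells of this form cannot be told apart, since only these 2 WT libraries have this code form.

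In 426 groups of 5 values, 41 had 1 library far from its nearest neighbour for the range of the group, and chance gives about 1 in 20 groups, 21.3 here. In WT, replicate 3 stood out for Il18 (6.5 CPM, nearest 9.36), Ptprd (2.19, nearest 0.457), Col5a1 (25.7, nearest 8.05), Eng (47.5, nearest 55.8), Col6a1 (22.1, nearest 7.99) and the number of genes with at least 10 counts (11863, nearest 11511). WT replicate 5 stood out for Trim12a (20.8 CPM, nearest 16.5), Lrmda (16.3, nearest 14.5) and Cyp51 (104, nearest 119), and WT replicate 2 for its total (18.34 M estimated counts, nearest 18.51 M).

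ROBO4_KO replicate 2 stood out for Vldlr (1.97 CPM, nearest 0.611), Col3a1 (6.73, nearest 0.586), Ptgs2 (5.07, nearest 0.906), Saa3 (0.0518, nearest 0.307), Thbs1 (165, nearest 25.1), Dkk3 (2.07, nearest 0.533) and Glb1 (106, nearest 113). The same library stood out for Col5a1 (14.9, nearest 2.66), Col6a1 (8.75, nearest 1.28), Fbn1 (16.7, nearest 0.944), Mgp (32, nearest 0.852), and the mean log2 levels of antiangiogenic factors (1.29, nearest -0.25) and extracellular matrix genes (2.79, nearest -0.21). ROBO4_KO replicate 1 stood out for Trim12a (19.1 CPM, nearest 15.9) and the level of cholesterol synthesis genes (-0.14, nearest 0.07), and ROBO4_KO replicate 3 for Atf3 (761 CPM, nearest 522).

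VLDLR_KO replicate 4 stood out for Npy (0.0558 CPM, nearest 0), Il10 (0.502, nearest 0.217), Lrpap1 (247, nearest 200), Hspa1b (2.06, nearest 1.01), Col6a1 (3.96, nearest 1.22) and Atf3 (514, nearest 340). VLDLR_KO replicate 2 stood out for Dynlt1b (136 CPM, nearest 86.8), Rpl29 (779, nearest 409), Atp5e (3.75, nearest 1.54) and the sum of its FPKM (676957, nearest 565679). VLDLR_KO replicate 1 stood out for Rab6b (0.272 CPM, nearest 0.0529), Adgre1 (1050, nearest 814), Eno1 (239, nearest 318), and the mean log2 levels of extracellular matrix genes (-2.93, nearest -0.91) and osteoblast and stromal genes (-2.23, nearest -0.41).

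Effects that differed between the code forms, by an interaction term in edgeR, numbered 1777 genes for VLDLR_KO against WT (1412 with opposite signs) and 47 for ROBO4_KO against WT (25 with opposite signs). Zfp36 had the smallest p in both, with differences of -3.33 (SE 0.16, adjusted p = 2.74e-07) and -3.29 (SE 0.16, adjusted p = 3.02e-07). For Qk the interaction was 0.16 (adjusted p = 0.628) in VLDLR_KO and -0.20 (adjusted p = 0.946) in ROBO4_KO, so no difference between forms was detected. The SE of the Qk interaction in VLDLR_KO was 0.21, so smaller differences could be missed. In simulated data this test recovered 0% of changes of 1.5-fold and 4.5% of those of 2-fold. The simulated spread included the difference between forms, which the interaction model takes out of the real counts. These shares therefore cannot say how many differences were missed here.

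Random groupings of single libraries did not give as many as the 1086 genes of VLDLR_KO against WT. The highest of the other 99 groupings gave 1 gene, and only 1 of 100, the real one, gave as many. The same held for the 39 genes of ROBO4_KO against WT, where 1 of 100 gave as many and the highest other gave 5. For VLDLR_KO against ROBO4_KO, with 888 genes, 2 of 100 gave as many, the real one included. The highest other, with 1592 genes, parted the libraries by code form (1 library with the digit after B on one side and 5 on the other), which points to the code form as a structure of the samples, and within the forms the real comparison gave 1500 and 1741 genes. Among the 47 groupings with 3 libraries of the form with the digit after B on each side, only the real one gave as many and the highest other gave 0. With the form as a covariate the real one gave 1868 and the highest other 7. These groupings treat each library as a separate unit, which the labels do not say. Chance differences between animals or cultures that several libraries share are therefore not excluded in any of the comparisons.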

How the results depend on the processing

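Leaving out WT replicates 1 and 2, VLDLR_KO replicates 1 and 2, WT replicate 3 with ROBO4_KO replicate 2, or the 3 libraries without Y-linked counts, and entering both covariates, were chosen only after the data were seen, and the other alternatives were planned.

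Counts of called genes stayed within 1.5 times the reported ones in 85 of 114 alternatives. They moved, for VLDLR_KO against WT (1086), ROBO4_KO against WT (39) and VLDLR_KO against ROBO4_KO (888), to 1678, 87 and 1394 with DESeq2, 5133, 1062 and 2833 with sample quality weights, and 1957, 75 and 1868 with the code form as a covariate. Within the forms they were 2442, 20 and 1500 (digit before B) and 1839, 188 and 1741 (digit after B), and with the form and the Y-linked share 1718, 66 and 1513. Without VLDLR_KO replicates 1 and 2 they were 2650, 60 and 1648. Fitting only the pair compared gave 713 and 507 for the comparisons with VLDLR_KO, a minimum log2 fold change of 1 gave 453 and 364, and an adjusted p under 0.01 gave 500, 21 and 424, as stricter thresholds must. Leaving out the 3 libraries without Y-linked counts gave 689 for VLDLR_KO against WT. Apart from stricter thresholds and fewer libraries, the cause was not tested. DESeq2 called all 1086 and 39 reported genes of the comparisons with WT and 886 of the 888. Leaving out each library in turn gave 738 to 1385, 29 to 48, and 639 to 1089 genes.

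Called Qk kept its direction in every alternative, but VLDLR_KO against WT missed the threshold with only the pair compared (-0.50, adjusted p = 0.0943), within the form with the digit before B (-0.65, 0.0501), with the Y-linked share (-0.52, 0.055), at an adjusted p under 0.01 (-0.50, 0.0301), on log2 FPKM (-0.49, 0.0514) and without WT replicates 1 and 2 (-0.39, 0.147). Leaving out 1 library gave -0.56 to -0.37, below the threshold for WT replicates 1, 2 and 4 and VLDLR_KO replicate 5 (adjusted p = 0.0619 to 0.0756). Against ROBO4_KO it missed with only the pair compared (-0.57, 0.058) and at an adjusted p under 0.01 (-0.57). Uncalled Qk in ROBO4_KO against WT changed sign with codes as blocks (-0.033) and within the form with the digit after B (-0.055).

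Slc17a5 passed for VLDLR_KO against WT with quality weights (-0.37, adjusted p = 0.0114) and against ROBO4_KO with the form as a covariate (-0.23, 0.0416). Its uncalled difference of ROBO4_KO from WT became negative with quality weights (-0.10) and without WT replicates 1 and 2 (-0.004), and that of Vldlr against ROBO4_KO positive with quality weights (0.29). Cxcl2 in VLDLR_KO against WT became positive with quality weights (0.44), within the form with the digit before B (1.05) and without WT replicates 1 and 2 (1.38, adjusted p = 0.0331; range 4.74e-06 to 0.765), Fosb without those libraries (0.32), and uncalled Fosb in ROBO4_KO against WT within the form with the digit before B (0.44). The cause was not tested. Of 143 called results of named genes 63 were never lost, 80 were lost in some alternative and 43 when 1 library was left out.

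Lists past the threshold numbered 5 for VLDLR_KO against WT, 0 with estimated correlations and 1 with fry (15 with fry for changes in either direction), and 3 (without WT replicate 2) to 8 (without VLDLR_KO replicate 2) when 1 library was left out. For ROBO4_KO against WT there were 12, 0 with estimated correlations, 0 with fry (also 0 in either direction), 7 without WT replicates 1 and 2, and 7 (without ROBO4_KO replicate 4) to 15 (without ROBO4_KO replicate 3). Between the knockouts 0 passed, against 2 with the form as a covariate, 1 with codes as blocks, 1 without WT replicates 1 and 2, 1 without WT replicate 3 and ROBO4_KO replicate 2, 1 without VLDLR_KO replicates 1 and 2, and 0 to 1 when 1 library was left out (1 without WT replicates 1 or 2, ROBO4_KO replicates 2 or 5, or VLDLR_KO replicates 3, 4 or 5). Immediate-early genes in VLDLR_KO against WT had a median of -0.006 without WT replicates 1 and 2, with the camera direction changed, and cell cycle genes in ROBO4_KO against WT -0.054 without ROBO4_KO replicate 5 (adjusted p = 0.879), within a range of -0.054 to 0.572 when 1 library was left out. Codes as blocks gave 1517, 51 and 1141 called genes, but libraries with the same code were no more alike (median r 0.38 over 12 pairs) than others of the same form (0.43 over 25 pairs).

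Shared calls of the knockouts numbered 26, and 55 with DESeq2, and 3, 6 and 9 (lowest, median and highest) with split WT libraries, where fewer libraries enter. Called transcripts numbered 1602, 164 and 1521 with DESeq2, and the cause was not tested. A filter on mitochondrial, ribosomal RNA and haemoglobin genes removed 0 tested genes and says nothing. Depth limits the targeted genes, since Robo4 had at most 4 counts and Vldlr at most 38 in a library.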

Other observations

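The comparisons of the code forms, of libraries by form for single genes, and of the share of Y-linked counts were chosen only after the results were seen, and the small gene lists were planned.

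Between the code forms, with genotype in the edgeR model, 2191 genes were higher and 2250 lower in libraries with the digit after B. Cell cycle genes were higher in these libraries in 39 of 40 members by call (median log2 difference 2.02, camera adjusted p = 1.03e-14, adjusted p = 0.687 with an estimated correlation). Neutrophil markers were higher in 7 of 8 by call (median 3.70, adjusted p = 3.07e-05, 0.279 with an estimated correlation), while interferon genes were lower in 18 of 27 (median -0.56, adjusted p = 1.11e-05, 0.687 with an estimated correlation). All 3 genotypes have libraries of both forms.

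The effects of Cd36, Lpl, Apoe and Csf1r, chosen after their values were seen, differed between the forms in VLDLR_KO against WT by an interaction term in edgeR (digit after B minus before: 3.39, adjusted p = 0.00038; 1.24, 0.0275; -2.09, 0.00143; -1.10, 0.000239). The scavenger receptor gene Cd36 had 1510 ± 353 CPM in WT (n = 3) and 95.2 ± 40.4 CPM in VLDLR_KO (n = 2) there, and 4170 ± 219 CPM (n = 2) and 2740 ± 844 CPM (n = 3) in the other form. The lipoprotein lipase gene Lpl had 4860 ± 870 and 1120 ± 55.5 CPM in the first form and 8220 ± 282 and 4480 ± 1630 CPM in the other. Apoe had 19300 ± 7920 CPM in VLDLR_KO libraries with the digit before B (n = 2) and 5540 ± 1000 CPM in the others (n = 3). The growth factor receptor gene Csf1r had 2440 and 1510 CPM in these libraries, against 1200 and 1580 CPM in WT.

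Of the 15 libraries, 3 (1 of WT, 2 of VLDLR_KO and 0 of ROBO4_KO) had nearly no counts of 4 Y-linked genes and the other 12 had at least 2083 each, and the labels used here give no sex. They were WT replicate 3 and VLDLR_KO replicates 3 and 4. WT replicate 3 was also the WT library with the highest level of extracellular matrix genes (2.89). The small lists had too few tested members for a test: B cells 3 of 18 (highest library 241 CPM), T and NK cells 4 of 21 (588 CPM), erythroid cells and megakaryocytes 2 of 19 (45 CPM), mast cells and basophils 2 of 14 (37.6 CPM), adipocytes 4 of 12 (586 CPM) and sex-linked genes 4 of 6 (101 CPM).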
